A study of Rattus norvegicus with 15 samples.

How the data were processed

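Lung RNA of rats was used in 15 libraries, 5 in each of 3 groups (control, ALI and SJY), grouped by their labels. The labels do not say whether a library holds 1 animal or a pool, and each was treated as 1 independent sample, so p-values measure the spread between these samples. They give no strain, dose, time after LPS or time of day, and name no group given the vehicle of the herbal formula. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made from 1 µg with the NEBNext Ultra RNA kit. The submitters' processing notes name cutadapt, HISAT2, StringTie and the rat genome build Rnor_6.0, with no versions and no strand setting. The deposited values are FPKM, per the file headers, with 1 column per library and 22250 genes with Ensembl identifiers. FPKM values carry no read counts, so depth is unknown, no counting interval can be given, and a value listed at 0 may be a failed estimate. No scaling between libraries is stated. No library was left out of the main tests.

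Gene symbols were taken from the deposited table, in which 8 genes had none and 148 symbols stood on more than 1 line. A reference list of rat genes from another genome build was used for synonyms only, and no coordinates or lengths are given because the builds differ. Checks of GC content and gene length were therefore not made. Genes that share reads with close copies (S100, metallothionein, hemoglobin, MHC and chemokine families) are uncertain, as is Naip6, which was matched to the symbol Naip2, and reads of overlapping genes on opposite strands may not have been told apart.

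FPKM values were turned into log2(FPKM + 1). Genes were kept at 1 FPKM or more in at least 5 of the 15 libraries, which left 13457. A fold change is on this log2(FPKM + 1) scale and understates the change of low genes. limma 3.58.1 in R 4.3.3 fitted all 3 groups together (lmFit, then eBayes with trend and robust settings), and the comparisons ALI against control, SJY against ALI and SJY against control were taken from that fit, two-sided. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, with no minimum fold. Means and SDs are of FPKM over the libraries of a group, and SEs are limma's. The test was run on simulated data with 200 of 13457 genes changed by known amounts, and the shares recovered are given with each comparison. The simulated noise was independent between genes, with 1 spread per gene over all groups and no outlying library. The shares can therefore overstate what the real data allow, and they differ between comparisons only by the random draw.

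The test, the samples, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule took, for each comparison, the 8 largest rises and 8 largest falls among called genes with a symbol, with all 5 libraries of a group above the 5 of the other and with a higher group mean of at least 5 FPKM. It also took, for each list, up to 3 called members per direction with the largest change, or, where none was called, the 3 with the highest mean. Obvious markers could be added. Genes picked in another way are said to be so.

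The 37 gene lists covered cytokines, chemokines, NF-kB, Toll-like receptor signalling, inflammasome, neutrophils, monocytes, alveolar macrophages, MHC class II and dendritic cells, T and NK cells, B cells, mast cells and eosinophils, alveolar type II and type I epithelium, airway cells, ciliated cells, endothelium, matrix, smooth muscle, interferon-induced genes, cell cycle, NRF2, hypoxia and glycolysis, complement and coagulation, acute phase proteins, junctions and channels, IL-17, PI3K and MAPK, eicosanoids, xenobiotic metabolism, glucocorticoid response, circadian clock, immediate early genes, blood, heart and skeletal muscle, adipose and mesothelium, and Y-linked genes. Some genes are in several lists, and a marker list does not measure a number of cells. For 24 listed genes no match was found, and these were not analysed here. Lists of at least 5 tested genes were tested with limma's camera with a preset inter-gene correlation of 0.01, adjusted over the 36 lists of a comparison, with camera with an estimated correlation and with fry beside it. Camera compares a list with the other genes, and fry asks whether its members move, on balance, 1 way. An exact permutation test of each list's mean over the 252 splits of 5 against 5 libraries was added.

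Comparisons against the same control libraries were set beside 20 simulated data sets without effects, the overlap of independent lists and 20 splits of the controls. The movement of LPS-changed genes toward control was measured by calling genes with 2 or 3 ALI libraries and comparing SJY with the others, over all 20 such choices. Alternatives were median-of-ratios scaling, limma without trend or robust settings, a pseudocount of 0.1, no filter, a minimum mean of 5 FPKM, a fit of only the groups compared, array weights, the replicate number as a block, a minimum fold of 2 and each library left out in turn. Added after the data were seen were mitochondrial genes removed with scaling, ALI 1 and SJY 1 left out together, and ALI 1 left out with scaling. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.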

Results

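Gene expression was measured by RNA sequencing in 15 libraries of rat lung, 5 in each of 3 groups. The control group was normal rats. The ALI group had acute lung injury from lipopolysaccharide (LPS, a component of bacterial cell walls) given into the trachea. The SJY group was given LPS and, by mouth, Sang Ju Yin, a herbal formula of traditional Chinese medicine. The table held 22250 genes as FPKM (fragments per gene, scaled for gene length and for the number of mapped fragments), so the number of reads behind each library, and the counting error of each value, are unknown. The sum of a library's values ran from 495244 FPKM in control 6 to 700068 FPKM in ALI 1, and 11865 to 13313 genes reached 1 FPKM. Mitochondrial genes took 8.11 ± 1.94% of the summed FPKM in control, 15.7 ± 12.6% in ALI and 12.4 ± 2.72% in SJY (SD, n = 5 each). ALI 1 stood apart at 37.7%, and the other ALI libraries had 10.2 ± 2.72% (SD, n = 4). Spearman correlations between libraries ran from 0.873 to 0.981 within groups and from 0.814 to 0.970 between groups. The first principal component of the 500 most variable genes held 46.1% of their variance and the second 19.97%.

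**Figure D1:**
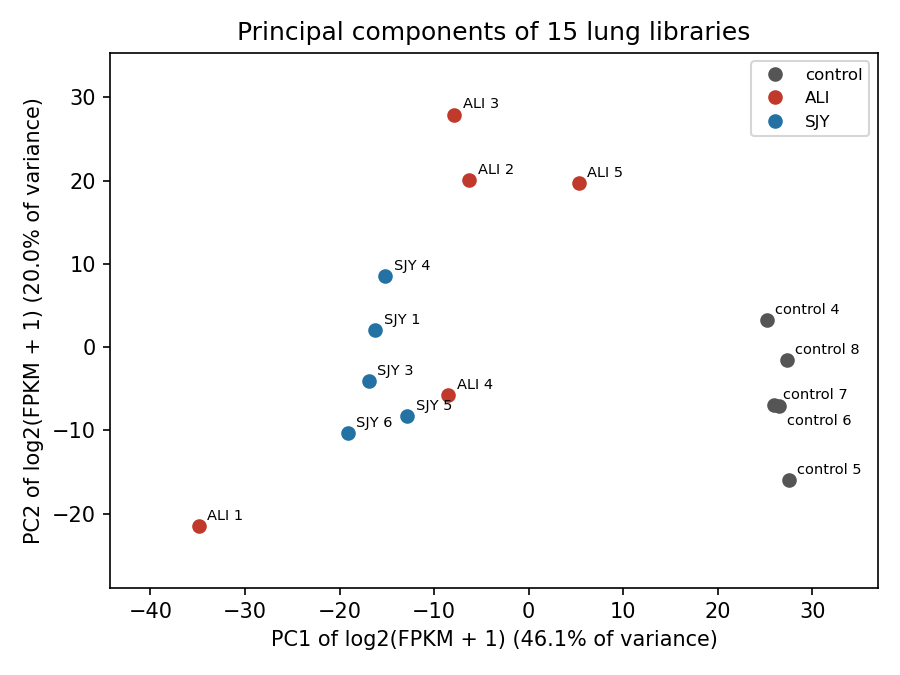
The first against the second principal component of the 500 most variable genes on the log2(FPKM + 1) scale, 1 point per library, coloured by group (5 control, 5 ALI and 5 SJY libraries). The axes hold 46.1% and 19.97% of the variance, and ALI 1 lies away from the other 4 ALI libraries, while ALI 4 lies near the SJY libraries.

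The comparison of ALI with control asks what LPS changed in the lung. No group given the instillation into the trachea without LPS is named beside the normal rats. Changes ascribed to LPS here may therefore include those of its instillation. Transcripts of neutrophils, acute phase proteins, chemokines and cytokines were higher in the injured lungs. Transcripts of the alveolar epithelium, of enzymes that metabolise foreign compounds and of most circadian clock genes were lower, though some clock genes rose. As lists, these lower ones lost their camera calls with an estimated inter-gene correlation (adjusted p from 0.278 to 0.361). They passed adjustment in the exact permutation test of list means (adjusted p = 0.0159 each). At an adjusted p under 0.05, limma called 2366 of 13457 genes, 1079 higher and 1287 lower in ALI, and 741 of them changed at least 2-fold (346 higher, 395 lower). In 1735 genes (12.9%) the values of the 5 ALI libraries all lay on 1 side of the 5 control libraries, against 0.794% by chance. The self-test recovered 64.2% of simulated changes of 1 log2 unit and 14.9% of those of 0.5 in this comparison. The median log2 change over all genes was −0.12, and −0.01 after median-of-ratios scaling, which called 1453 higher and 1302 lower. Camera compares members with the other genes and so allows for this shift, while fry and the exact permutation test do not. The count of changed genes was 1545 without control 5 and 1538 without control 7. It was 1332 when only the ALI and control libraries were fitted, and 3959 with array weights. Array weights are estimated from the same data and give less weight to libraries that deviate from their group.

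The 8 largest rises that met the rule for named genes were led by the calprotectin genes. S100a8 rose from 14.2 ± 7.50 FPKM in control to 1842 ± 1819 FPKM in ALI (SD, n = 5 each; log2 fold change 6.60 ± 0.49 SE, adjusted p = 1.57e-06), and S100a9 from 37.3 ± 9.68 to 3647 ± 3679 FPKM (log2 fold change 6.10). The acute phase gene Orm1 rose from 0.234 ± 0.192 to 125 ± 151 FPKM and the B cell chemokine Cxcl13 from 7.33 ± 3.17 to 568 ± 410.2 FPKM. The neutrophil collagenase Mmp8 (log2 fold change 4.94), the decoy receptor Il1r2 (4.82), the secreted phospholipase Pla2g2a (4.33) and Prok2 (4.23) followed. The large SDs in ALI came partly from ALI 1, which held 5022 FPKM of S100a8 and 387 FPKM of Orm1. Reads shared between S100 paralogs could have been split by the authors' counting, so single S100 values are uncertain.

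The 8 largest falls that met the rule were led by Fmo2. This flavin monooxygenase gene fell from 904 ± 182 FPKM in control to 149 ± 91.5 FPKM in ALI (SD, n = 5 each; log2 fold change −3.01 ± 0.54 SE, adjusted p = 0.00163). Aldh1a1 fell from 229.5 ± 35.3 to 40.8 ± 23.6 FPKM and Cyp2f4 from 50.2 ± 28.3 to 8.31 ± 7.76 FPKM. Susd2 (log2 fold change −2.77), the amino acid transporter Slc7a10 (−2.73), the endothelial gene Esm1 (−2.63), Cyp2a1 (−2.57) and Krt76 (−2.45) also fell.

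Myeloid and inflammatory gene lists moved upward almost without exception among their called members. Of 24 neutrophil markers tested, 21 rose and 1 fell (22 and 1 adjusted over the list alone; camera adjusted p = 1.25e-23). Cxcr1 was the marker that fell, from 11.6 ± 2.81 to 4.04 ± 1.44 FPKM (SD, n = 5 each). Of 18 IL-17 pathway genes, 13 rose and 0 fell (15 and 1 adjusted over the list alone; camera adjusted p = 6.47e-12). Of 20 acute phase and antimicrobial genes, 15 rose and 1 fell (16 and 1 adjusted over the list alone; camera adjusted p = 1.09e-13), and Chi3l1 rose from 48.7 ± 10.1 to 447 ± 107 FPKM. Of 25 chemokines, 14 rose and 1 fell (15 and 3 adjusted over the list alone; camera adjusted p = 1.34e-07). Ccl19 rose by 3.33 log2 units and Cxcl14 fell by 1.06. Of 15 cytokines, 8 rose and 0 fell (9 and 0 adjusted over the list alone; camera adjusted p = 1.91e-05). Il1b went from 18.9 ± 6.36 to 93.0 ± 24.3 FPKM, and Csf3, listed at 0 in 4 control libraries and at 0.0637 FPKM in control 6, stood at 58.4 FPKM in ALI 1 and at 0.896 to 16.6 FPKM in the other 4 ALI libraries. Of 23 NF-kB pathway and feedback genes, 14 rose and 0 fell (16 and 0 adjusted over the list alone; camera adjusted p = 1.17e-12), among them Cebpb and Zc3h12a. Of 21 monocyte and recruited macrophage markers, 13 rose and 0 fell (13 and 0 adjusted over the list alone; camera adjusted p = 1.34e-07), with Vcan up by 2.67 log2 units.

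Complement, inflammasome and eicosanoid genes rose in part. Of 25 complement and coagulation genes, 11 rose and 1 fell (12 and 1 adjusted over the list alone; camera adjusted p = 1.04e-06), and C3 went from 51.4 ± 14.7 to 250.2 ± 85.6 FPKM (SD, n = 5 each). Of 16 inflammasome and pyroptosis genes, 6 rose and 0 fell (7 and 0 adjusted over the list alone; camera adjusted p = 3.37e-05), and Nlrp3 rose from 4.61 ± 0.300 to 9.48 ± 0.636 FPKM. Of 18 genes of arachidonic acid metabolism, 8 rose and 1 fell (8 and 2 adjusted over the list alone; camera adjusted p = 0.0013). These 3 lists and the 7 in the paragraph on myeloid and inflammatory lists kept their calls with an estimated inter-gene correlation, with adjusted p from 0.0288 to 0.0494. The other 16 called lists lost theirs. By fry 21 of 36 lists passed, and 20 passed adjustment in the exact permutation test. Among those 20 were the glucocorticoid (adjusted p = 0.0159) and NRF2 (0.0301) lists, which camera did not call.

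**Figure D2:**
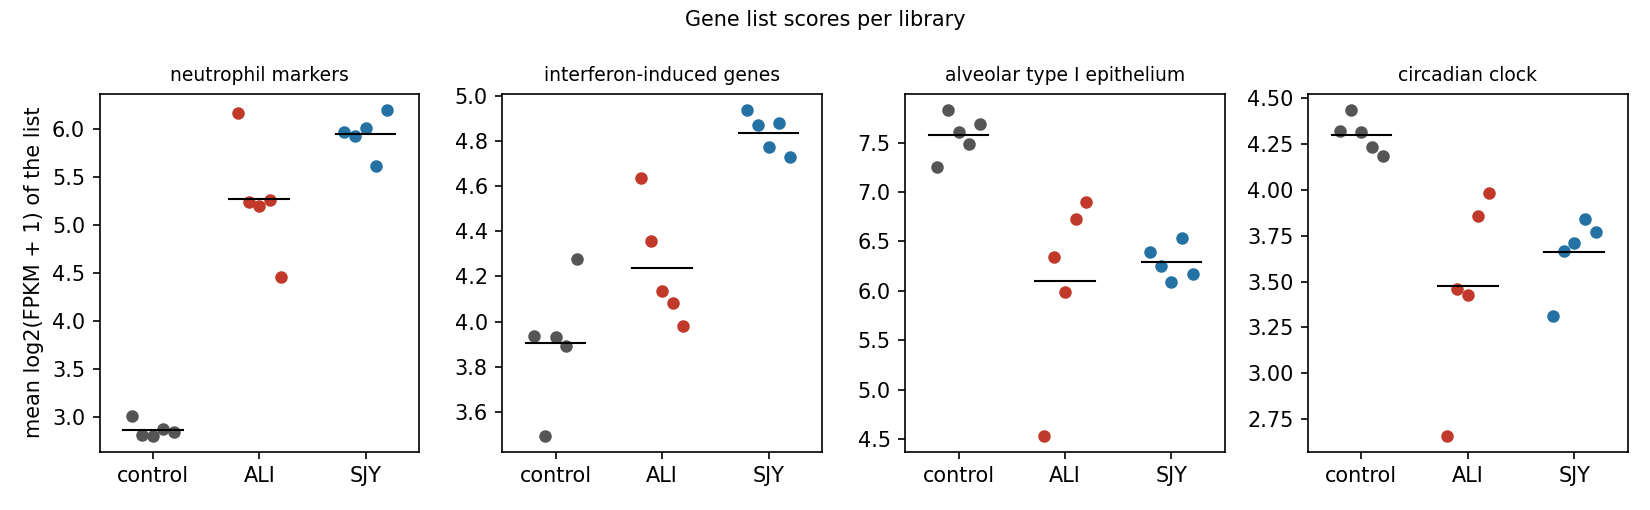
Mean log2(FPKM + 1) of the tested members of 4 gene lists (neutrophil markers, interferon-induced genes, alveolar type I epithelium and circadian clock) in each library, 1 point per library with the group mean as a line. All 5 ALI and all 5 SJY libraries lie above the 5 control libraries for neutrophil markers.

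Both alveolar epithelial lists were lower. All 16 alveolar type I genes fell (0 up and 16 down adjusted over the list alone; camera adjusted p = 3.06e-08, and adjusted p = 0.278 with an estimated correlation). Spock2, Akap5 and Rtkn2 had the largest falls of the list, by 2.20, 1.97 and 1.94 log2 units. Of 18 alveolar type II and surfactant genes, 0 rose and 7 fell (0 and 11 adjusted over the list alone; camera adjusted p = 2e-04, and adjusted p = 0.361 with an estimated correlation). The complement gene C5 of that list fell from 11.9 ± 2.40 to 2.34 ± 1.54 FPKM (SD, n = 5 each). Of 22 epithelial junction, water and ion channel genes, 0 rose and 11 fell (1 and 12 adjusted over the list alone; camera adjusted p = 0.00218, and adjusted p = 0.369 with an estimated correlation). The sodium channel gene Scnn1a fell from 221 ± 35.7 to 94.1 ± 36.6 FPKM. Of 21 xenobiotic metabolism genes, 2 rose and 13 fell (2 and 14 adjusted over the list alone; camera adjusted p = 0.000519, and adjusted p = 0.361 with an estimated correlation). Of 15 ciliated cell genes, 0 rose and 5 fell (0 and 6 adjusted over the list alone; camera adjusted p = 0.0339, and adjusted p = 0.64 with an estimated correlation). The call for ciliated genes was lost without control 4 (adjusted p = 0.086), control 7 (0.0845), ALI 2 (0.187) or ALI 4 (0.123). Part of the fall of several of these lists came from ALI 1. Its mean log2(FPKM + 1) of type I genes was 4.54 (5.98 to 6.89 in the other ALI libraries, 7.25 to 7.83 in control). That of junctions and channels was 4.20 (4.90 to 5.14 and 5.19 to 5.44), and that of xenobiotic metabolism 3.06 (4.44 to 4.88 and 5.14 to 5.41).

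The circadian clock list was lower as a whole, with its members going both ways. Of 17 clock genes, 3 rose and 10 fell (3 and 11 adjusted over the list alone; camera adjusted p = 0.00516, and adjusted p = 0.332 with an estimated correlation). Per2 fell from 39.7 ± 5.01 to 8.43 ± 4.90 FPKM (SD, n = 5 each), Per3 from 36.3 ± 2.32 to 9.21 ± 8.03 FPKM and Tef from 69.8 ± 14.3 to 20.9 ± 15.1 FPKM, while Arntl rose from 3.61 ± 1.25 to 9.13 ± 1.75 FPKM. Of 16 immediate early genes, 0 rose and 6 fell (0 and 6 adjusted over the list alone; camera adjusted p = 0.00347, and adjusted p = 0.361 with an estimated correlation), and Nr4a1 fell by 1.23 log2 units. Of 17 glucocorticoid-responsive genes, 4 rose and 4 fell, the same numbers as adjusted over the list alone (camera adjusted p = 0.477). The mean of that list was 0.37 and its median −0.30. Mt2A rose by 4.14 log2 units and Klf9 fell by 1.11.

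Proliferation, matrix and glycolysis genes were higher. Of 27 cell cycle genes, 13 rose and 0 fell (19 and 0 adjusted over the list alone; camera adjusted p = 5.49e-10, and adjusted p = 0.278 with an estimated correlation), and Mcm5 went from 3.27 ± 0.667 to 9.71 ± 3.12 FPKM (SD, n = 5 each). Of 23 fibroblast and extracellular matrix genes, 10 rose and 1 fell (10 and 2 adjusted over the list alone; camera adjusted p = 3.37e-05, and adjusted p = 0.176 with an estimated correlation). Timp1 rose from 34.4 ± 12.5 to 315 ± 161 FPKM and Dcn from 49.7 ± 7.06 to 185 ± 40.1 FPKM, while Ccn2 fell from 217 ± 19.3 to 52.4 ± 21.7 FPKM. Of 21 hypoxia and glycolysis genes, 9 rose and 2 fell (10 and 2 adjusted over the list alone; camera adjusted p = 2.32e-05, and adjusted p = 0.139 with an estimated correlation). Of 20 Toll-like receptor signalling genes, 5 rose and 0 fell (7 and 0 adjusted over the list alone; camera adjusted p = 0.000104, and adjusted p = 0.176 with an estimated correlation), with Cd14 going from 29.9 ± 5.04 to 107 ± 29.3 FPKM. Of 18 genes of MHC class II presentation and dendritic cells, 1 rose and 0 fell, the same numbers as adjusted over the list alone (camera adjusted p = 0.00516, and adjusted p = 0.361 with an estimated correlation).

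The remaining lists changed little or rested on single libraries. Of 28 interferon-induced genes, 2 rose and 0 fell, the same as adjusted over the list alone (camera adjusted p = 0.00445, and adjusted p = 0.408 with an estimated correlation). The camera call was lost without ALI 1 (adjusted p = 0.0955) and without control 5 (adjusted p = 0.06). Of 19 alveolar macrophage markers, 7 rose and 1 fell (8 and 1 adjusted over the list alone; camera adjusted p = 0.0289, and adjusted p = 0.332 with an estimated correlation). This call was lost without ALI 1 (adjusted p = 0.11), without control 5 (adjusted p = 0.0719) and with median-of-ratios scaling (adjusted p = 0.0509). Of 19 B cell and plasma cell markers, 0 rose and 1 fell, the same as adjusted over the list alone (camera adjusted p = 0.0289 upward, 0.646 with an estimated correlation, and 0.436 without ALI 3, where the list's mean went from 0.40 to −0.0058). Of 10 blood genes, limma called 0, or 0 adjusted over the list alone, with 3 at an unadjusted p under 0.05, all higher (camera adjusted p = 0.0294, and adjusted p = 0.416 with an estimated correlation). This call was lost without ALI 1 (adjusted p = 0.102), ALI 2 (0.0784), control 4 (0.0838), control 7 (0.0657) or control 8 (0.0713), and with median-of-ratios scaling (0.0509).

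The other lists had no camera call in this comparison. Of 21 endothelial genes, 2 rose and 4 fell, as they did adjusted over the list alone (camera adjusted p = 0.304). Of 13 airway club, goblet and basal cell genes, 0 rose and 4 fell (2 and 5 adjusted over the list alone; camera adjusted p = 0.582, but 0.00974 without ALI 3). Of 24 PI3K, AKT and MAPK components, 3 rose and 2 fell, as they did adjusted over the list alone (camera adjusted p = 0.811). Of 22 NRF2 and oxidative stress genes, 6 rose and 6 fell (6 and 7 adjusted over the list alone; camera adjusted p = 0.582), with a mean of 0.24 and a median of −0.12. Of 20 T cell and NK cell markers, 0 rose and 1 fell (0 and 0 adjusted over the list alone; camera adjusted p = 0.767, with 1 higher and 1 lower at an unadjusted p under 0.05). None of 16 smooth muscle and pericyte genes was called by limma, over all genes or adjusted over the list alone, with 1 higher and 1 lower at an unadjusted p under 0.05 (camera adjusted p = 0.479), and Acta2 stood at 152 ± 48.0 FPKM in control and 157 ± 64.2 FPKM in ALI (SD, n = 5 each). Of 7 mast cell, basophil and eosinophil markers 0 rose and 1 fell (0 and 2 adjusted over the list alone; camera adjusted p = 0.63), and of 7 heart and skeletal muscle genes 1 rose and 0 fell, as adjusted over the list alone (camera adjusted p = 0.326). Of 7 adipose and mesothelial genes 1 rose and 1 fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.767 upward, with a mean of −0.02 and a median of −0.27). The Y-linked and X-inactivation list had 2 tested genes, too few for camera, and 1 of them rose, as it did adjusted over the list alone. At an unadjusted p under 0.05 by limma, 1 of the 2 was also higher in SJY than in control, and 0 differed between SJY and ALI. Whether the groups differed in sex was not tested.

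The comparison of SJY with ALI asks what oral Sang Ju Yin changed in the LPS-treated lung. With all 15 libraries, 1 gene passed the threshold. By camera with a preset correlation, the lists of interferon-induced genes, neutrophil markers and inflammasome genes were higher in SJY than in ALI, and those of MHC class II presentation and of B cells were lower. None of these 5 calls held with an estimated correlation (smallest adjusted p = 0.391), 1 passed by fry, and the mean of the B cell list changed sign without ALI 3. How many single genes differed depended on ALI 1. The T and NK cell protease gene Gzma (ENSRNOG00000010603) rose from 24.1 ± 6.71 FPKM in ALI to 70.4 ± 16.9 FPKM in SJY (SD, n = 5 each; log2 fold change 1.51 ± 0.22 SE, adjusted p = 0.0437), with all 5 SJY libraries above all 5 ALI libraries, and stood at 16.7 ± 5.01 FPKM in control. At an unadjusted p under 0.05 limma gave 1587 genes, against 672.9 by chance among 13457. In 435 genes (3.23%) the 2 groups of 5 libraries did not overlap, against 0.794% by chance. These chance figures are averages without a spread. Genes vary together within libraries, so an arbitrary split can exceed them, and the excess does not show an effect of SJY. For called genes, 8 of 100 splits, the real one included, gave as many or more. The self-test, whose simulated data hold no library like ALI 1, recovered 74.6% of changes of 1 log2 unit and 8.96% of those of 0.5 in this comparison. The call of Gzma was lost with median-of-ratios scaling, with a pseudocount of 0.1, with no filter on low values, without the trend and robust settings of limma and when only the ALI and SJY libraries were fitted, each of which called 0 genes. The count was also 0 without control 4, 6 or 7, SJY 1, 3, 4 or 6, or ALI 3 or 5. Without ALI 4 the call of Gzma was lost too (adjusted p = 0.0566) and 1 other gene, Nlrp12, was called (log2 fold change 1.53, adjusted p = 0.0417). Without control 5 there were 5 genes, Gzma, Retnlg (1.41), Herc6 (0.85) and Olr1 (0.74) higher and Rab12 (−0.95) lower. These 5 names beside Gzma were chosen after their values were seen.

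Without ALI 1, 181 genes differed between SJY and the other 4 ALI libraries, 119 higher and 62 lower in SJY, and array weights gave 478 (297 higher, 181 lower). The genes given here were picked from those 181 after their values were seen. Among the higher ones, the chemokine Ccl12 rose from 6.17 ± 1.75 FPKM in ALI (SD, n = 4) to 31.4 ± 11.5 FPKM in SJY (SD, n = 5; log2 fold change 2.13 ± 0.29 SE, adjusted p = 0.00578). The interferon-induced genes Ifit3 (log2 fold change 1.77), Irf7 (1.46), Isg15 (1.37) and Mx2 (1.34) and the neutrophil genes S100a9 (1.66), Prok2 (1.55), Mmp8 (1.38), Cxcr2 (1.27) and Csf3r (1.20) were higher too. Among the lower ones were the immune receptor Fcrl2 (log2 fold change −3.16), Lbh (−1.38), Cd4 (−1.26), Apoe (−1.26), elastin (Eln, −1.25) and the complement gene C1qb (−1.08). In ALI 1 itself, Ifit3 stood at 133 FPKM and S100a9 at 10067 FPKM, above their SJY means of 74.1 and 5825 FPKM, while C1qb stood at 19.2 FPKM, below its SJY mean of 82.2 FPKM. Of the higher genes named, Mx2 (19.9 FPKM), Cxcr2 (79.3) and Csf3r (113) lay in ALI 1 below their SJY means of 32.5, 91.5 and 173 FPKM. The rest of them lay above.

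Over all 5 ALI libraries, 27 of 28 interferon-induced genes were higher in SJY, with 0 called by limma, 16 adjusted over the list alone and 17 at an unadjusted p under 0.05 (camera adjusted p = 4.58e-13). Bst2 stood at 186 ± 51.2 FPKM in ALI and 336 ± 60.5 FPKM in SJY (SD, n = 5 each; adjusted p = 0.151), and Ifi27 at 283 ± 80.6 and 513 ± 92.9 FPKM (adjusted p = 0.194). Of 24 neutrophil markers, 22 were higher in SJY, with 0 called by limma, 9 adjusted over the list alone and 14 at an unadjusted p under 0.05 (camera adjusted p = 5.78e-09). Of 18 genes of MHC class II presentation and dendritic cells, 15 were lower, with 0 called, 3 adjusted over the list alone and 6 at an unadjusted p under 0.05 (camera adjusted p = 5.29e-05), and Cd74 stood at 2071 ± 681 FPKM in ALI and 1498 ± 386 FPKM in SJY (adjusted p = 0.424). B cell and plasma cell markers were lower with 0 called, 0 adjusted over the list alone and 2 at an unadjusted p under 0.05 (camera adjusted p = 0.00471, but 0.789 without ALI 3, where the list's mean went from −0.37 to 0.042). Inflammasome and pyroptosis genes were higher with 0 called, 1 adjusted over the list alone and 3 at an unadjusted p under 0.05 (camera adjusted p = 0.0364). That call was lost with median-of-ratios scaling (adjusted p = 0.112) and without ALI 3 (0.0872), ALI 4 (0.0811), ALI 5 (0.111), SJY 4 (0.0898) or SJY 6 (0.0702). With an estimated correlation camera gave an adjusted p of 0.391 for the interferon list and 0.566 each for the neutrophil and MHC class II lists. It gave 0.581 for the inflammasome list and 0.984 for the B cell list. By fry, only the interferon list passed (adjusted p = 0.0448). An exact permutation test of each list's mean, two-sided over the 252 splits of 5 against 5, gave p = 0.00794 for the interferon list, the smallest it can give, and p = 0.0397 each for the neutrophil, inflammasome and NRF2 lists. None of the 36 lists passed adjustment in that test (smallest adjusted p = 0.286).

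The other 31 lists had no camera call between SJY and ALI over all libraries. Alveolar type I genes differed by a mean of 0.19 log2 units (adjusted p = 0.391, and 0.044 without ALI 5) and alveolar type II genes by 0.13 (adjusted p = 0.459). Without ALI 1 both means changed sign, to −0.20 (adjusted p = 0.749) and −0.10 (0.914). Cytokines differed by 0.19 (adjusted p = 0.326, and 0.0116 without ALI 1) and NF-kB genes by −0.07 (adjusted p = 0.522, and 0.044 without ALI 5). Without ALI 1, 10 lists were called, of which 1 held with an estimated correlation, the NRF2 and oxidative stress list (higher, camera adjusted p = 0.000229, and adjusted p = 0.0335 with an estimated correlation). The other 9 had adjusted p from 0.0627 to 0.754 there. In that setting 11 of 24 neutrophil markers and 8 of 28 interferon-induced genes were called higher, 4 of 23 matrix genes lower (camera adjusted p = 0.00187) and 3 of 21 hypoxia and glycolysis genes higher (camera adjusted p = 0.000624). IL-17 pathway genes were called higher (adjusted p = 0.0394, and adjusted p = 0.754 with an estimated correlation). Cell cycle genes were called lower without ALI 4 (0.00456). In 6 lists (monocytes, airway cells, smooth muscle, acute phase, IL-17, and PI3K, AKT and MAPK) the mean, the median and the camera direction differed in sign, all with a mean within 0.15 log2 units of 0.

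**Figure D3:**
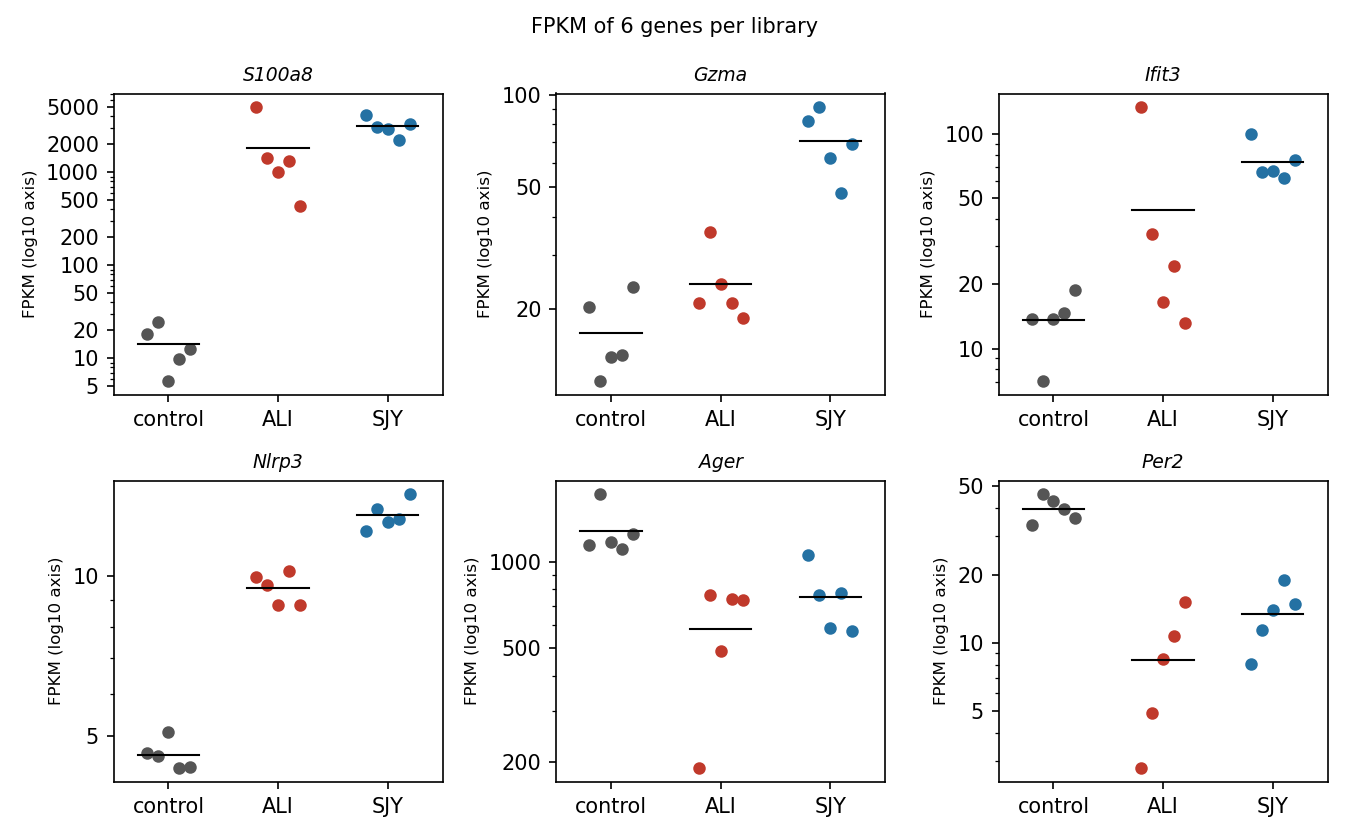
FPKM of 6 genes (S100a8, Gzma, Ifit3, Nlrp3, Ager and Per2) in each library on a log10 axis, 1 point per library with the group mean as a line (n = 5 per group). Gzma is higher in all 5 SJY libraries than in all 5 ALI libraries, and S100a8 is higher in all ALI and SJY libraries than in control.

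The comparison of SJY with control asks what still differed from normal lung in animals given LPS and Sang Ju Yin. The direction of change was that of LPS alone, with myeloid and acute phase transcripts high and epithelial ones low, and interferon-induced genes were high as well. As lists, 23 were called by camera, and 1 of these calls held with an estimated correlation. By fry 23 of 36 lists passed, and 25 passed adjustment in the exact permutation test. The test called 4390 of 13457 genes, 1959 higher and 2431 lower in SJY, and 1142 of them changed at least 2-fold (474 higher, 668 lower). In 3730 genes (27.7%) the groups did not overlap, against 0.794% by chance. The self-test recovered 70.1% of simulated changes of 1 log2 unit and 13.4% of those of 0.5. Array weights raised the count to 7654. A larger count than for ALI against control does not show a larger response, since the difference between SJY and ALI has its own test above.

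S100a8 rose to 3126 ± 681 FPKM in SJY from 14.2 ± 7.50 FPKM in control (SD, n = 5 each; log2 fold change 7.80 ± 0.49 SE, adjusted p = 9.35e-08), and S100a9 rose by 7.27 log2 units. The other largest rises were in Mmp8 (log2 fold change 5.90), Il1r2 (5.69), Ifitm6 (5.68), Prok2 (5.44), Orm1 (5.25) and Cxcl13 (4.79). Ifitm6 went from 3.59 ± 1.81 to 226 ± 48.3 FPKM and stood at 63.4 ± 53.2 FPKM in ALI. The largest falls were in Spock2 (log2 fold change −3.02), Fmo2 (−2.95), Susd2 (−2.71), Fosb (−2.69), Zbtb16 (−2.59), the cytokine receptor Lifr (−2.54), Cyp2e1 (−2.45) and Scube2 (−2.36). The call of Cyp2e1 was lost with a pseudocount of 0.1 (adjusted p = 0.0558). Marco, a macrophage scavenger receptor, was listed at 0 in all 5 control libraries and at 1.54 to 4.89 FPKM in SJY.

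Of 24 neutrophil markers, 22 rose and 1 fell, as they did adjusted over the list alone (camera adjusted p = 1.14e-21, and adjusted p = 0.0731 with an estimated correlation). Of 28 interferon-induced genes, 19 rose and 1 fell (20 and 1 adjusted over the list alone; camera adjusted p = 4.45e-09, and adjusted p = 0.123 with an estimated correlation), and Ifit3 went from 13.6 ± 4.17 to 74.1 ± 15.3 FPKM (SD, n = 5 each). Of 16 inflammasome and pyroptosis genes, 8 rose and 0 fell, as adjusted over the list alone (camera adjusted p = 2.75e-05, and adjusted p = 0.0731 with an estimated correlation). Of 15 cytokines, 9 rose and 0 fell, as adjusted over the list alone (camera adjusted p = 2.81e-05), the 1 of 23 called lists that held with an estimated correlation (adjusted p = 0.0353). Of 16 alveolar type I genes, 0 rose and 13 fell (0 and 14 adjusted over the list alone; camera adjusted p = 2.81e-05), and of 18 alveolar type II genes 0 rose and 9 fell (0 and 10 adjusted over the list alone; camera adjusted p = 0.0126). Both alveolar calls were lost with an estimated correlation (adjusted p = 0.391 for type I and 0.573 for type II), and that for type II also by fry (0.0656). Of 20 T cell and NK cell markers, 3 rose and 1 fell, as adjusted over the list alone (camera adjusted p = 0.906), and Cd8a went from 16.8 ± 2.09 to 36.2 ± 10.4 FPKM. Of 17 clock genes, 2 rose and 9 fell, as adjusted over the list alone (camera adjusted p = 0.019, and adjusted p = 0.391 with an estimated correlation), with Per2 at 13.5 ± 4.13 FPKM. The calls for alveolar macrophage markers and immediate early genes were lost without ALI 1 (adjusted p = 0.0575 each). Those for immediate early genes were also lost without control 4 (0.119), control 5 (0.055) or SJY 4 (0.0514), and that for blood genes was lost without SJY 1 (0.0693). In 5 lists without a call (MHC class II, T cells, B cells, mast cells and glucocorticoid response) the mean, the median and the camera direction differed in sign.

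Of the 2366 genes called between ALI and control, 1967 (83.1%) were called in the same direction between SJY and control, 946 higher and 1021 lower, and 0 in opposite directions, by limma in both. Independent lists of these sizes would share 157 higher and 232 lower genes. Across genes, which are not independent replicates, the 2 sets of log2 fold changes had r = 0.877, against 0.499 in simulated groups without any effect against the same controls. Their covariance was 0.316, against 0.0291 in the simulation, and the difference of 0.287 estimates the part that comes from a shared effect. With the controls split between the comparisons, r was 0.782, the covariance 0.297, and 109 genes were called higher and 16.5 lower in both (medians over 20 splits), against 16.3 and 3.59 for independent lists.

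Whether genes changed by LPS moved back toward control in SJY was measured with ALI libraries that had not been used to call the genes. Over 20 splits of the ALI libraries, SJY minus the other ALI libraries was compared in sign with the LPS change. The signs were opposite for a median of 38.2% of called genes (13.2% to 57.4%), against 39.0% of genes not called. Distance to control was not compared, so a gene that went past control counts as well. The share was 29.1% for genes that rose with LPS and 46.9% for genes that fell. The median change from control was 0.72 log2 units in the other ALI libraries and 0.85 in SJY for genes that rose, and −0.81 and −0.84 for genes that fell. These values depended on ALI 1. The share was 21.3% when ALI 1 was among the libraries that called the genes (24.3% of genes that rose and 19.2% of those that fell), against 35.0% of genes not called in the same splits. It was 47.7% when ALI 1 was among those compared (29.7% and 71.2%), against 47.1% of genes not called. Without ALI 1 it was 27.2% (17.8% to 45.3% over 6 splits; 30.6% and 22.1%), against 36.9%. For genes that fell, the medians in the other ALI libraries and in SJY were −0.48 and −0.73 with ALI 1 among the calling libraries, and −1.12 and −0.89 with it among those compared, so their order depended on 1 library. For genes that rose they were 0.62 and 0.85, and 0.82 and 0.87. A movement of the called genes as a whole toward control was not detected.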

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

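The 2 tests of ALI 1 and the counts over other splits of the samples were set before their results were seen, and 1 verdict changed afterwards, as told with its test. Each library was compared with the other 4 of its group by Dixon's ratio, for 4 library measures, 36 list scores and 80 genes named in the text, which made 360 groups of 5. In 37 of them a library lay far from the others. Chance alone gives about 1 in 20 independent groups. These groups share libraries and genes, and some of the genes, such as those called without ALI 1, were picked after their values were seen. The 37 can therefore not be weighed against that rate. ALI 1 accounted for 15 of the 37, control 4 for 7, SJY 1 for 6, and the others for 3 or fewer each.

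ALI 1 had 37.7% of its summed FPKM in mitochondrial genes (8.31% to 14.1% in the other ALI libraries), 39.4% in its top 10 genes (15.1% to 18.6%) and 11865 genes at 1 FPKM or more (12945 to 13313). Its mean log2 values were low for the lists of matrix (4.78), smooth muscle (3.04), complement and coagulation (4.51), junctions and channels (4.20), PI3K, AKT and MAPK (4.23) and xenobiotic metabolism (3.06). Among genes, ALI 1 was low for Acta2 (47.1 FPKM), Aldh1a1 (5.66 FPKM), Cd4 (7.27 FPKM) and Cxcr1 (1.57 FPKM), and high for Il1b (135.6 FPKM) and Marco (1.96 FPKM). SJY 1 had the highest sum of its group (657641 FPKM), 17.1% in mitochondrial genes, 23.1% in its top 10 genes and 12305 genes at 1 FPKM or more. It was low for Cd4 (11.6 FPKM) and Zc3h12a (22.9 FPKM).

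Control 4 had a sum of 554527 FPKM (495244 to 501656 in the other controls) and a high score of mast cell, basophil and eosinophil markers (3.18). It was low for C3 (26.7 FPKM), Cxcl6 (0.0482 FPKM), Fmo2 (580.3 FPKM), Lbh (30.6 FPKM) and Lifr (9.62 FPKM). Control 5 was low for the inflammasome (3.28) and complement (4.10) lists and high for Ager (1722 FPKM). Control 6 had 0.0637 FPKM of Csf3, listed at 0 in the other controls, and control 8 had 45.7 FPKM of Nr4a1. SJY 4 was high for C1qb (110.9 FPKM), Eln (71.0 FPKM) and Marco (4.89 FPKM), and ALI 2 had a high score of glucocorticoid-responsive genes (6.90).

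The distance of ALI 1 from the other ALI libraries was weighed first. With mitochondrial genes removed and the libraries rescaled, ALI 1 was still the outlying ALI library for 1429 genes, against 112 for the next ALI library (1925 before that step), so a large mitochondrial share that only dilutes other transcripts is not the whole cause. Its median Spearman correlation was 0.909 with SJY, 0.888 with the other ALI libraries and 0.834 with control. The outcome stated for a library of another group was a higher correlation with that group by more than 0.02, which was met for SJY. The outcome stated against it, a correlation below a set bound with every group, was met too. That bound was badly chosen, since a library of low quality correlates less with every group, so this test does not settle the label. The value of Gzma, picked after it was seen, goes against an SJY library under the ALI label. ALI 1 had 20.9 FPKM of Gzma (47.8 to 91.0 FPKM in SJY, 18.7 to 35.5 FPKM in the other ALI libraries). Its 35.6 FPKM of Il6 lay above SJY (2.62 to 5.96 FPKM) and above the other ALI libraries. Its scores of smooth muscle (3.04) and alveolar type I genes (4.54) lay below those of SJY (4.37 to 4.58 and 6.09 to 6.54). They also lay below those of the other ALI libraries (4.63 to 4.86 and 5.98 to 6.89). Values outside both groups do not bear on the label. Other scores, also picked after they were seen, were nearer SJY. The neutrophil score of ALI 1 was 6.17 (5.61 to 6.20 in SJY, 4.46 to 5.27 in the other ALI libraries). Its interferon score was 4.63 (4.73 to 4.94 in SJY, 3.98 to 4.36 in the other ALI libraries). A poor library and a more severe injury cannot be told apart, and a wrong label is left open, since a poor library of either group could depart in such genes. The design names no factor that separates ALI 1 from its group, so no biological explanation was tested.

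Other splits of the samples were then counted. For ALI against control, 1 of 100 splits, the real one, gave 2366 genes or more. This is the smallest share that 100 splits can give, so chance is an unlikely source of this count. The highest other split, with control 4 and ALI 1 to 4 on 1 side, gave 1850 genes; it differs from the real one by a single exchange. For SJY against control, 1 of 100 splits, the real one, gave 4390 genes, the highest other gave 1, and chance is again an unlikely source. For SJY against ALI, 8 of 100 splits gave as many as the 1 gene of the real split, so chance cannot be excluded. There the highest other split gave 110 genes, with SJY 1, SJY 3, ALI 1, ALI 2 and ALI 4 on 1 side, several times the real count. This may point to a structure among these 10 libraries, but it is the highest of 100 splits (median of the others 0 genes, with 7 of them calling any), and no structure was tested.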

How the results depend on the processing

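The settings that removed mitochondrial genes with scaling, left out ALI 1 and SJY 1, or left out ALI 1 with scaling were chosen after the data were seen. Between ALI and control, the 2366 called genes became 1332 when only these groups were fitted, 3959 with array weights and 741 at a fold of at least 2. Leaving out each library gave 1538 (control 7) to 2890 (ALI 5). Between SJY and control, the 4390 genes became 7654 with array weights and 1142 at a fold of at least 2, and 3329 to 5953 with each library left out. Apart from the replicate block, given below, the remaining settings stayed within 1.5 times of both counts. The fold minimum lowers a count by its own construction, and for the others the cause was not tested.

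Between SJY and ALI, the 1 called gene became 0 with median-of-ratios scaling, 0 without trend or robust settings, 0 with a pseudocount of 0.1, 0 with no filter, 0 when only these groups were fitted, and 0 with mitochondrial genes removed and scaling. It became 478 genes with array weights, which give ALI 1 a weight of 0.0889. Leaving out ALI 1 and SJY 1 gave 58 genes, and leaving out ALI 1 with scaling gave 176. Leaving out each library gave 0 to 181, the highest without ALI 1. The cause was not tested beyond ALI 1.

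Of the lists camera called, 26 between ALI and control became 10 with an estimated correlation, and 23 to 26 with each library left out. For SJY against ALI, 5 became 0 with an estimated correlation, 1 by fry, 12 without ALI 1 and SJY 1 and 9 without ALI 1 with scaling, and 3 to 10 with each library left out. For SJY against control, 23 became 1 with an estimated correlation, and 21 to 23 with each library left out. The share of LPS-changed genes that moved toward control, by sign, stayed within its SD of 14.4 points over splits. It was 27.2% to 44.8% with no split of the ALI libraries, a pseudocount of 0.1, no filter, a fold of at least 2, median-of-ratios scaling or without ALI 1, the settings run for it. With each SJY library left out it was 34.1% to 42.0%.

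The groups share some replicate numbers, but no pairing of the samples by number was seen, and 9 pairs are too few to exclude one. Control 7, control 8 and ALI 2 share their number with no other library, so they add nothing to a group difference in the block fit. Deviations of same-numbered libraries had correlations of −0.389 to 0.302 (median 0.0562, 9 pairs, 3 of them over 0.1). The 66 other pairs had a median of 0.00722, with 14 over 0.1. Most samples correlated best with another number (ALI 3 with SJY 4, at 0.446, for example). With the replicate block, ALI against control gave 313 genes (244 higher and 69 lower), SJY against control 1142 (743 higher and 399 lower; without the block both had more lower than higher), SJY against ALI 1 gene, and SJY against ALI 2 called lists.

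Among named genes, 112 of 118 were called between ALI and control, 47 of them under every setting and 86 under every setting but the block. Between SJY and control these were 133, 70 and 112. No called named gene changed direction. The mean of the B cell list changed sign without ALI 3, with no call there, and the cause was not tested. With each library left out it ran from −0.0058 (without ALI 3) to 0.69 for ALI against control and from −0.65 to 0.042 (without ALI 3) for SJY against ALI. Depth is unknown, so no limit from counting can be given.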

Other observations

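The tests of scaling and of ALI 1 alone on the interferon list and both tests of the clock genes were chosen after those results were seen. The genes in the next paragraph were picked after their values were seen.

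The neutrophil chemokine receptors moved apart. Cxcr2 went from 3.09 ± 0.887 FPKM in control to 48.0 ± 23.4 FPKM in ALI and 91.5 ± 18.7 FPKM in SJY (SD, n = 5 each), while Cxcr1 went from 11.6 ± 2.81 to 4.04 ± 1.44 and 3.89 ± 0.934 FPKM. Nlrp3 had little spread within groups and stood apart in all 3, at 4.61 ± 0.300, 9.48 ± 0.636 and 13.02 ± 0.805 FPKM (adjusted p = 0.163 between SJY and ALI by limma). The ALI means of several cytokine genes were set by ALI 1. Il6 stood at 35.6 FPKM in ALI 1 and at 0.633 to 5.14 FPKM in the other 4 ALI libraries, with 4.07 ± 1.38 FPKM in SJY, and Cxcl6 stood at 100.4 FPKM in ALI 1 and at 2.55 to 35.4 FPKM in the others, with 2.12 ± 1.30 FPKM in SJY.

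The interferon list was higher in SJY than in ALI by a mean of 0.60 log2 units. Its camera call was lost with an estimated correlation (adjusted p = 0.391) and it did not pass adjustment in the exact permutation test (0.286), so what follows holds only if the difference is real. The authors' scaling of the libraries does not account for this, since the difference was 0.57 after median-of-ratios scaling and camera still called the list. Leaving out ALI 1 was no real test, as its outcome was fixed. The interferon score of ALI 1 (4.63) was the highest of its group (3.98 to 4.36 in the other ALI libraries). The difference could therefore only widen without ALI 1, and it was 0.70. ALI 1 raised the ALI mean, so it did not produce the difference. More neutrophils in the SJY samples would raise both lists together. With the neutrophil score of each library as a covariate, the difference was 0.38 ± 0.16 (SE), and 0.56 ± 0.26 without ALI 1. Both lie more than 2 SE from 0, the outcome stated beforehand for a difference that neutrophils do not carry alone. The score measures neutrophils imprecisely, and its slope was 0.32 ± 0.15 (SE), and 0.15 ± 0.24 without ALI 1. Adjusting for such a score can remove too little, so this test cannot decide the question. That neutrophils carry a part or all of the difference stays open, as it fell from 0.60 to 0.38. What else raised the list was not tested, and a difference between the groups in the time or dose of LPS, which the labels do not give, stays open. For the neutrophil list itself no cause was tested beyond these.

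The clock genes in ALI moved in 2 directions. The mean of Arntl, Clock and Npas2 was higher by 0.70 log2 units (exact permutation p = 0.00794, two-sided, the smallest that 252 splits can give). An equal dilution of all clock genes by other cells would lower each of them, so it alone does not give this. The rise was known when the test was chosen, and other changes in the mix of cells were not tested. The Per, Dbp, Tef, Hlf and Nr1d genes were lower by a mean of −1.52 (exact permutation p = 0.00794) while Arntl and Npas2 were higher by 1.08 and Clock was not higher (−0.054, adjusted p = 0.766 by limma). Opposite movement of both arms is consistent with sampling at another time of day or with a clock shifted by LPS, and these cannot be separated without the times of sampling. In SJY the activators (Arntl, Clock and Npas2) differed from control by 0.22 (exact permutation p = 0.151). Arntl and Npas2 without Clock differed by 0.49 (exact permutation p = 0.0397). The Per, Dbp, Tef, Hlf and Nr1d genes differed by −0.95 (exact permutation p = 0.00794). The activators minus this other arm differed by 1.17 (exact permutation p = 0.00794). Between SJY and ALI the activators differed by −0.48 (exact permutation p = 0.0238), and Arntl and Npas2 without Clock by −0.59 (exact permutation p = 0.0556). The other arm differed by 0.57 (exact permutation p = 0.302), and the activators minus the other arm by −1.05 (exact permutation p = 0.111). Whether the activators of SJY differed from control or from ALI at p under 0.05 thus depended on counting Clock. The permutation p-values are unadjusted over the 12 tests of this family.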
